A study of Mus musculus with 80 samples.

How the data were processed

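Livers of 80 mice were profiled by RNA sequencing, 5 in each of 16 groups set by genotype (wild type or Adamts12 knockout), treatment (CCl4 or vehicle) and time after injection (4 h, 12 h, 24 h or 7 days). Per the labels, CCl4 was given at 0.3 ml per kg, 3% by volume in olive oil, and libraries were made from 500 ng of total RNA with a stranded mRNA protocol and sequenced on a NovaSeq in random order. The labels number the mice and the replicates, but no pairing or shared day between groups is given. The libraries of equal number were not closer to each other than to other libraries, and replicate number was used as a block only as an alternative.

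The authors named STAR, HTSeq, DESeq2 and the mouse build GRCm38, without versions. The deposited values are normalized signal, which the authors made by dividing read counts per gene by a size factor per library. One table holds 14560 genes for each of the 80 libraries. Within each library every value was a whole multiple of a single step within a tolerance of 0.01, and dividing by that step gave the totals of 18.6 to 64.5 M reads per library. These totals were used to describe depth and were not used in a test. A value of 0 allows up to 3 reads of a library. Genes were matched by identifier to GENCODE M21, which placed 14552 of 14560, and 2 genes had no symbol. No pair of libraries was identical, and the highest correlation between libraries (0.9897 on the log2 scale) came with a chi-square of 29.2 per degree of freedom, which is far above the 1 that repeated sequencing of a library gives.

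Genes with at least 10 normalized counts in at least 5 libraries were kept, which removed 2 and left 14558. Values were analysed as log2 of the value plus 1 with limma 3.58.1 in R 4.3.3, in a model with a mean for each of the 16 groups, fitted to all 80 libraries with an empirical Bayes variance prior with trend. The median residual SD was 0.363 on the log2 scale, with 68.6 total degrees of freedom. Contrasts compared CCl4 with vehicle within each genotype and time, the difference of these effects between the genotypes, and the genotypes within CCl4 and within vehicle livers. F tests asked for a difference of the CCl4 effect between times in wild type, for an interaction at any time, and for a difference between the times among vehicle livers of each genotype. The two-sided p values were adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p under 0.05 were called. The Adamts12 level was also tested by permuting genotype within each condition 100000 times.

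Gene lists, 33 with 571 genes of liver cell types, zonation, stress responses, metabolism, matrix and cell cycle, were fixed from general knowledge beforehand, as were the contrasts, the thresholds and the rule for named genes. Of their genes 515 were measured, and lists with at least 2 tested genes were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the lists within a contrast. The same test with an estimated correlation called 0 lists in any contrast. The lists were called 194 times in total at the preset correlation, and regrouped libraries gave as many in 60 of 100 regroupings. These regroupings redrew genotype and treatment together within each time, so the redrawn contrasts hold part of the CCl4 effect. They cannot tell how many calls chance alone gives. The member counts, over all genes and adjusted over the list alone, lead the description and were not regrouped. No list was chosen on these samples.

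Genes were named by a rule. Adamts12 was named in every group. For each contrast the 10 largest rises and 10 largest falls were named among called genes with a symbol, a mean of at least 100 normalized counts in a compared group and, for contrasts of a pair of groups, no overlap of the 5 and 5 values, and predicted genes need not be described. For each list up to 4 members with the smallest adjusted p were named, and for a result on 5 genes or fewer each gene. For the genotype difference over vehicle livers the 20 called genes with the largest change and at least 100 counts were named. Some genes that met the rule are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

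The pipeline was tested on simulated data with known changes. In a simulated copy of the 4 h wild-type comparison, 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. Some were raised and others lowered. Of these 58.2%, 85.1% and 98.5% were recovered, with 6 unchanged genes among 167 calls. The changed genes had means of at least 100 counts and genes varied independently, so recovery in the real livers may be lower. For the 4 h interaction the recovery was 20.9%, 68.7% and 95.5%, and for the interaction at any time 9%, 46.3% and 90.9%. A list of 20 changed genes was called, and 0 of 30 random lists were.

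Alternatives fixed before the data were examined were a pseudocount of 8, no filter beyond a value above 0 in 5 libraries, a filter on a mean of 100 counts, TMM scaling factors, quantile normalization, a fit of each time alone, array weights, a variance prior without trend, replicate number as a block, an added threshold of 1 on the absolute log2 change, leaving out the wild-type mice numbered below 7000, an estimated correlation for lists, and leaving out each library in turn. Leaving out libraries that stood apart from their groups was added after seeing the data. Tests on whole reads, edgeR and DESeq2, were planned and not run here, since the counts per library rest on an inferred step. Tables were handled with the data.table package (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Ddx3y, Kdm5d, Uty and Eif2s3y of the Y-linked list were not among the measured genes, and that list was not tested.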

Results

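RNA was sequenced from 80 livers of C57BL/6J mice that were wild type or lacked Adamts12, a gene for a secreted metalloproteinase of the extracellular matrix. Each mouse, labelled female, received a single intraperitoneal injection of carbon tetrachloride (CCl4), a hepatotoxin that is activated by cytochrome P450 in pericentral hepatocytes, or of olive oil as vehicle. Livers were taken at 4 h, 12 h, 24 h or 7 days, which gave 16 groups of 5 livers. Values were normalized read counts per gene and library. Recovered totals ranged from 18.6 to 64.5 M reads per library, with a median of 32.75 M, and the 10 most abundant genes held 15.1% to 28.6% of the counts. Unless stated otherwise, changes are log2 differences ± SE between groups of 5 livers, and gene groups are lists of known markers or pathway members. The SE of a gene rests on a spread estimated over all 16 groups, and not on the livers compared alone. That spread includes knockout libraries of 12 h that, as described below, stood with the other treatment.

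The first question was whether the knockout livers had less Adamts12 transcript. Adamts12 (ENSMUSG00000047497, chromosome 15, 11064790 to 11349231, GRCm38) was a low-abundance transcript, with 23.6 ± 16.6 normalized counts (SD, n = 40) in wild-type livers and 8.2 ± 5.4 (SD, n = 40) in knockout livers. Over the 8 conditions it was lower in the knockout by a log2 difference of -1.39 ± 0.16 (limma adjusted p = 2.18e-09), and its mean was lower in 8 of 8 conditions. A two-sided permutation test within conditions gave p = 1e-05, the smallest that 100000 permutations can give. In wild-type livers Adamts12 rose at 24 h after CCl4, from 16.9 ± 5.7 to 58.1 ± 18.4 counts (SD, n = 5; log2 change 1.72 ± 0.45, adjusted p = 0.00109). The knockout value at 24 h also rose, from 5.5 ± 4.1 to 11.5 ± 2.8 (log2 change 1.19 ± 0.45, adjusted p = 0.0263), and the interaction term did not differ from 0 (adjusted p = 0.999). The values of the genotypes overlapped in 7 of 8 conditions, all but CCl4 at 24 h, for example at 12 h after CCl4, with up to 25.4 counts in the knockout and 11.4 to 18.9 in wild type. With a pseudocount of 8 the difference over the 8 conditions was -0.88, and Adamts12 was still called. The labels do not say which part of the gene was removed, so the remaining counts were not assigned to exons.

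**Figure D1:**
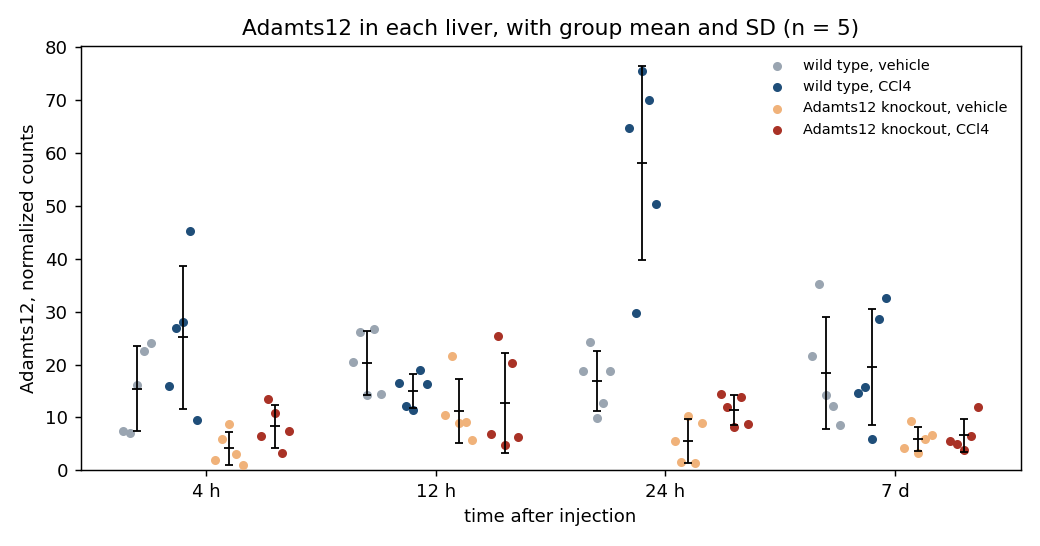
Normalized Adamts12 counts in each of the 80 livers, by genotype, treatment and time, with group means (n = 5). The wild-type mean after CCl4 is highest at 24 h, at 58.1 counts, and the knockout mean lies below the wild-type mean in 8 of 8 conditions.

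The response of wild-type liver to CCl4 was asked at each time against vehicle livers of the same time. At 4 h, transcripts of the heat shock, integrated stress and p53 responses had risen. Hspa1a, an inducible HSP70 chaperone, went from 10.2 ± 12.6 to 2526.9 ± 1648.4 counts (SD, n = 5; log2 change 8.05 ± 0.67). The stress-induced transcription factor Atf3 went from 111.5 ± 39.1 to 14163.2 ± 6086.0 (6.94 ± 0.97). Fgf21, a hepatic stress hormone, rose by 7.50 ± 0.73, and Cdkn1a, the p21 cell cycle inhibitor, by 6.12 ± 0.45. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 5176.8 ± 1727.8 to 283.6 ± 114.8 counts (-4.21 ± 0.89). In total 5896 of 14558 tested genes changed, 3202 higher and 2694 lower. With quantile normalization 45% of the changed genes were higher in place of 54.3%, so the larger direction depended on the scaling.

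The largest rises at 4 h also included Sprr1a, a cornified envelope protein (9.51 ± 1.78, with 412 counts in vehicle replicate 1 and 0 to 4 in the other 4), Hspa1b (7.23 ± 0.52) and Dusp5, a phosphatase that acts on ERK (7.02 ± 0.80). Bhlha15, a transcription factor of secretory cells (6.32 ± 0.75), Srxn1, which restores oxidized peroxiredoxins (6.00 ± 0.62), and Psat1, an enzyme of serine synthesis (5.89 ± 0.82), followed. The largest falls were those of the clock output factor Dbp (-5.07 ± 0.71), the imprinted RNA H19 (-4.45 ± 1.40), the clock gene Per3 (-4.34 ± 0.44), the deubiquitinase Usp2 (-3.90 ± 0.31) and the adrenergic receptor Adrb3 (-3.61 ± 0.69). Krt23 (-3.13 ± 0.84) and Nrep (-3.07 ± 0.64) also fell. Among these genes the adjusted p was at most 0.00782 (H19).

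Among gene groups at 4 h, all 12 tested heat shock proteins rose, among them the co-chaperones Dnajb1 (4.72 ± 0.34) and Bag3 (3.01 ± 0.24). In the unfolded protein and integrated stress response 18 of 20 members rose and 1 fell, with Sesn2 at 3.48 ± 0.34, the chaperone Hspa5 at 3.07 ± 0.31 and Ppp1r15a at 3.97 ± 0.47. Immediate early genes rose in 14 of 18 cases, including Ier5 (3.24 ± 0.24) and Ccn1 (5.21 ± 0.53). Of 19 p53 targets 10 rose and 2 fell, with Mdm2, which limits p53, at 2.58 ± 0.19 and Gdf15 at 3.98 ± 0.51. Of 20 NRF2 targets 8 rose and 1 fell, among them Hmox1, which degrades haem (3.30 ± 0.32). Of 20 pericentral hepatocyte genes 6 fell and 0 rose, including the zonation factors Tbx3 (-2.75 ± 0.32) and Lgr5 (-2.28 ± 0.35). By camera the adjusted p values of these 6 lists, in this order, were 2.88e-15, 2.34e-09, 1.69e-08, 0.00252, 0.0215 and 0.00481. With an estimated correlation none of the 6 was called, with adjusted p values of 0.0726, 0.131, 0.214, 0.131, 0.648 and 0.851. Adjusted over the list alone, the counts were the same except for 15 immediate early genes and 11 p53 targets that rose.

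The clock list moved in both directions at 4 h, with 4 of 20 genes higher and 9 lower, the same counts when adjusted over the list alone (camera adjusted p = 0.164). The activators Arntl and Npas2 rose by 4.14 ± 0.33 and 4.35 ± 0.52. Chemokines and cytokines rose in 6 of 21 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.232). Monocyte and macrophage markers rose in 2 of 18 cases, or 1 adjusted over the list alone (camera adjusted p = 0.708).

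At 12 h the number of changed genes in wild type was 8365, 4165 higher and 4200 lower. Metabolic enzymes of the pericentral zone had dropped. Glul, glutamine synthetase of the cells around the central vein, fell from 48696.2 ± 7055.1 to 4830.5 ± 741.6 counts (SD, n = 5; log2 change -3.34 ± 0.44). Cyp2e1, the main cytochrome that activates CCl4, fell from 183990.8 ± 18780.0 to 38941.6 ± 6656.5 (-2.25 ± 0.31). Sprr1a went from 383.8 ± 852.0 to 50730.0 ± 15440.3 counts (11.97 ± 1.78), and the small heat shock protein Hspb1 from 504.1 ± 620.8 to 36491.2 ± 8310.2 (6.82 ± 0.95). Vehicle replicate 1 raised both vehicle means, with Sprr1a at 1908 counts against 2 to 6 in the other 4 vehicle livers and Hspb1 at 1603 against 114 to 325.

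Other large rises at 12 h were those of Atf3 (7.76 ± 0.97), Pwwp3b (7.45 ± 1.03), the glutathione transferase Gsta1 (7.14 ± 1.09), the serine synthesis enzymes Phgdh (6.61 ± 1.07) and Psat1 (6.39 ± 0.82), and the growth factor Bmp8b (6.56 ± 0.89). Large falls were seen for the steroid-metabolizing cytochromes Cyp3a16 (-6.22 ± 1.47), Cyp3a41b (-5.99 ± 1.12) and Cyp3a41a (-4.81 ± 1.62), the sulfotransferases Sult3a2 (-5.53 ± 1.07) and Sult3a1 (-5.28 ± 1.18), and Nxpe2 (-5.47 ± 0.72). Idi1, an enzyme of isoprenoid synthesis, fell by 4.11 on the log2 scale (SE 0.58), and Cyp8b1, which forms cholic acid, fell by 3.54 (SE 0.66). The adjusted p was at most 0.00895 (Cyp3a41a).

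Of 20 pericentral genes 19 fell and 1 rose at 12 h, with Oat, an enzyme of ornithine breakdown, at -3.55 ± 0.41. Of 18 periportal genes 11 fell, such as the urea cycle enzymes Otc (-1.98 ± 0.33) and Arg1 (-1.22 ± 0.25). Cholesterol synthesis and uptake fell in 17 of 20 genes. Bile acid genes fell in 15 of 18 cases, among them the uptake carriers Slc10a1 (-2.31 ± 0.33) and Slco1b2 (-2.69 ± 0.42). Of 20 PPARalpha and fatty acid oxidation genes 12 fell and 4 rose, with Hadha at -1.41 ± 0.19 and the thioesterase Acot2 at 3.40 ± 0.46. For these 5 lists the camera adjusted p was 2.35e-06, 0.00112, 2.35e-06, 0.000123 and 0.0112. With an estimated correlation each had an adjusted p of 0.517. The counts were the same adjusted over the list alone.

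Members of several stress lists were also higher than in vehicle livers at 12 h. All 12 heat shock proteins, 11 of 20 NRF2 targets, 13 of 20 unfolded protein and integrated stress response genes and 11 of 18 immediate early genes rose, and 1 gene of each of the last 3 lists fell. Examples were the mitochondrial chaperones Hspe1 (2.76 ± 0.30) and Hspd1 (1.80 ± 0.21), the stress factor Ddit3 (4.79 ± 0.56) and the pseudokinase Trib3 (4.98 ± 0.62). The camera adjusted p was 2.35e-06, 0.00067, 0.00112 and 0.000602, and with an estimated correlation the adjusted p was 0.517 for each. Adjusted over the list alone, 14 genes of the unfolded protein list rose and 2 fell, and the other counts were the same.

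Markers of non-parenchymal cells moved at 12 h as well. Sinusoidal endothelial markers fell in 16 of 18 cases, with the scavenger receptor Stab2 at 554.6 ± 244.0 against 2247.0 ± 797.9 counts (SD, n = 5; -2.02 ± 0.30) and the VEGF receptor Kdr at -1.70 ± 0.33. Kupffer cell markers fell in 9 of 13 cases, or 10 adjusted over the list alone, for example Cd163 (-2.17 ± 0.50). Quiescent stellate cell markers fell in 7 of 15 cases, and extracellular matrix genes fell in 13 of 26 and rose in 1. Cytokines and chemokines rose in 13 of 21 cases and fell in 1, led by Cxcl10, a chemokine for T cells (4.05 ± 0.60). Interferon-stimulated genes rose in 12 of 23 cases and fell in 2. In the acute phase list 13 of 23 genes fell and 1, the endotoxin receptor Cd14, rose (3.29 ± 0.60). Acute phase genes of wild-type vehicle livers themselves changed with time in 22 of 23 cases, as described below. The falls are thus relative to oil-injected livers of 12 h, and no uninjected liver was measured. Camera adjusted p values for these 7 lists were 0.000123, 0.02, 0.0194, 0.0146, 0.0213, 0.0473 and 0.0146. With an estimated correlation the adjusted p values were 0.517, 0.551, 0.517, 0.551, 0.551, 0.678 and 0.62. Apart from the Kupffer cell list, the counts adjusted over the list alone were the same.

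At 24 h Cyp2e1 stood at 26682.5 ± 13440.1 counts against 281265.0 ± 44896.5 in vehicle livers (SD, n = 5; log2 change -3.55 ± 0.31), and Slc1a2, a pericentral glutamate transporter, fell by 5.70 on the log2 scale (SE 0.40). Lgals3, a galectin of activated macrophages, went from 450.1 ± 192.5 to 8347.6 ± 3892.8 (4.09 ± 0.55), and Mmp12, macrophage elastase, from 20.8 ± 22 to 864.7 ± 100.9 (5.88 ± 0.91). Ccnd1, cyclin D1, went from 733.8 ± 181.8 to 3570.2 ± 613.2 (2.30 ± 0.35). In total 7163 genes changed, 3680 higher and 3483 lower. Without the wild-type mice numbered below 7000 in the labels, which leaves a single vehicle liver, the count was 1302. Of the 5 vehicle mice of 24 h 4 had such numbers and of the 5 CCl4 mice 0, so within wild type the CCl4 effect at 24 h is mixed with any difference between mice of low and high number. No knockout mouse had such a number, and of the genes changed at 24 h 2320 rose and 2626 fell in both genotypes and 0 changed in opposite directions, so such a difference does not account for the whole effect.

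Gsta1 was listed at 0 in all 5 vehicle livers at 24 h and averaged 960.4 ± 657.2 counts (SD, n = 5) after CCl4. Other large rises were those of Sprr1a (11.39 ± 1.78), Prrg4 (6.80 ± 0.75), Bmp8b (6.57 ± 0.89), the cystine transporter Slc7a11 (6.56 ± 1.07), the fatty acid elongase Elovl7 (6.26 ± 0.68), the stress protein Nupr1 (6.24 ± 0.76) and Aldh1l2, a mitochondrial folate enzyme (6.12 ± 0.86). Large falls were seen for Cpsf4l (-6.66 ± 0.66), Cyp7a1 (-6.45 ± 0.89), the sulfotransferases Sult2a7 (-6.40 ± 0.76) and Sult3a1 (-5.76 ± 1.18), Cyp8b1 (-5.90 ± 0.66), the uridine phosphorylase Upp2 (-5.42 ± 0.66) and Ptk6 (-5.38 ± 0.73). The adjusted p was at most 5.09e-05 (Sult3a1).

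Of 20 pericentral genes 17 fell and 1 rose at 24 h, with Glul at -4.34 ± 0.44, and of 18 periportal genes 13 fell and 1 rose, with the urea cycle enzyme Asl at -1.95 ± 0.27. Cholesterol genes fell in 19 of 20 cases, such as Mvk (-2.79 ± 0.41) and Fdft1 (-2.45 ± 0.41), and bile acid genes in 16 of 18. By camera the adjusted p was 2.87e-09, 0.000264, 3.85e-08 and 1.07e-08, and with an estimated correlation the adjusted p was 0.286, 0.424, 0.329 and 0.286. Adjusted over the list alone, 15 periportal, 20 cholesterol and 17 bile acid genes fell, and the other counts were the same.

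Monocyte and macrophage markers rose in 13 of 18 cases at 24 h, including Cd63 (4.16 ± 0.59) and Cd9 (1.99 ± 0.28). Cytokines and chemokines rose in 16 of 21 cases and fell in 1, with Ccl4, a chemokine for monocytes, at 4.13 ± 0.71. Interferon-stimulated genes rose in 16 of 23 cases and fell in 1, with Ifi27l2a at 1.99 ± 0.43. The camera adjusted p was 1.5e-05, 8.56e-05 and 0.00206, and with an estimated correlation the adjusted p was 0.329, 0.329 and 0.545. The counts were the same adjusted over the list alone. Sinusoidal markers fell in 8 of 18 cases, or 7 adjusted over the list alone (camera adjusted p = 0.0173, adjusted p = 0.651 with an estimated correlation).

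At 24 h DNA replication genes rose in 13 of 21 cases and fell in 1, with cyclin E1 (Ccne1) at 2.64 ± 0.38. Mitosis genes rose in 10 of 21 cases, with the spindle protein Prc1 at 2.13 ± 0.63. TGF-beta targets and ligands rose in 11 of 18 cases and fell in 1, with Id1 at 2.81 ± 0.38 and Thbs1, a matrix protein that activates TGF-beta, at 3.83 ± 0.72. Of 26 matrix genes 6 rose, with Col12a1 at 2.93 ± 0.38. By camera the adjusted p was 0.000956, 0.0141, 0.00248 and 0.036, and with an estimated correlation the adjusted p was 0.329, 0.651, 0.286 and 0.651. Adjusted over the list alone, 14 replication and 12 TGF-beta genes rose, and the other counts were the same. The direction of the matrix list turned without the mice numbered below 7000 (adjusted p = 0.809, range over its alternatives 0.0169 to 0.809). In the family of ADAMTS and MMP proteases with their inhibitors 6 of 25 members rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.73). Mmp13, a collagenase, rose by 5.86 ± 0.75, and Adamts1 by 1.84 ± 0.34.

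**Figure D2:**
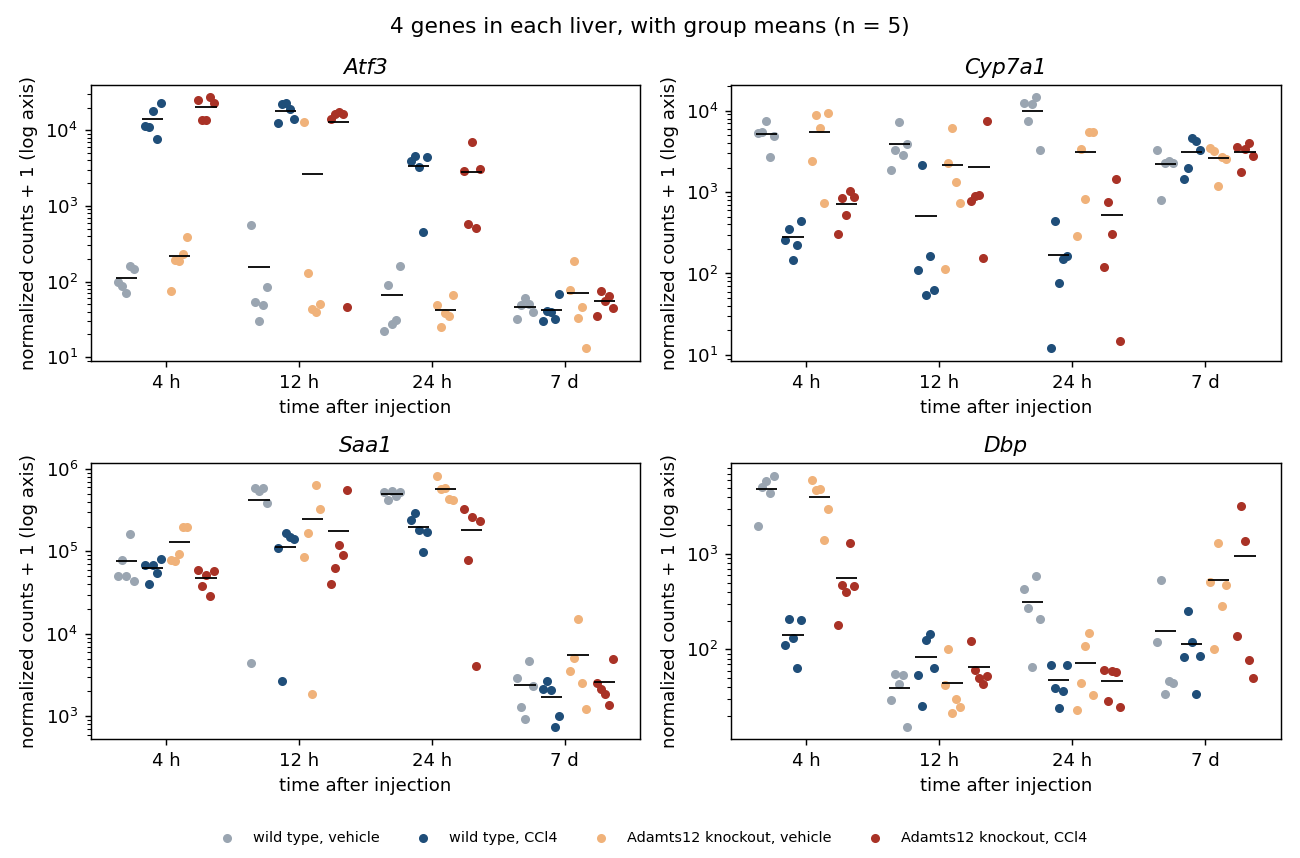
Normalized counts of Atf3, Cyp7a1, Saa1 and Dbp in each liver by time, genotype and treatment, with group means (n = 5). Atf3 in wild-type CCl4 livers averaged 14163.2 counts at 4 h and 18263.3 at 12 h, and Cyp7a1 averaged 169.1 at 24 h.

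By 7 days few wild-type genes differed from vehicle, 3 higher and 4 lower at an adjusted p under 0.05, and 2193 genes had an unadjusted p under 0.05. More of the CCl4 mice than of the vehicle mice were numbered below 7000, so treatment is partly mixed with mouse number here. The mitochondrial isoleucine tRNA mt-Ti was higher, at 194.2 ± 178.7 against 36.1 ± 16.7 counts (SD, n = 5; 2.20 ± 0.43, limma adjusted p = 0.0145). Mcm4, a subunit of the replicative helicase, was lower, at 116.7 ± 31.3 against 246.9 ± 78.1 (-1.08 ± 0.22, adjusted p = 0.0162). Among 21 DNA replication genes 1 fell, or 9 adjusted over the list alone (camera adjusted p = 3.31e-08, adjusted p = 0.281 with an estimated correlation). No mitosis gene and no sinusoidal marker passed over all genes, while 9 of 21 and 11 of 18 fell adjusted over the list alone (camera adjusted p = 4.17e-11 and 6.97e-09, adjusted p = 0.538 for both with an estimated correlation). The count of 7 genes was 2, 1 and 550 without CCl4 replicates 2, 3 and 4, and 2 and 1 without vehicle replicates 1 and 2. The direction of the mitosis list turned without the mice numbered below 7000, which leaves a single CCl4 liver (adjusted p = 0.129, range over its alternatives 6.22e-14 to 0.538).

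Whether the CCl4 effect in wild type differed between the 4 times was tested for each gene with an F test, and it did for 8802 of 14558 genes. All 12 heat shock proteins and all 20 cholesterol genes were among them, as were 19 of 20 clock genes, 19 of 21 replication genes and 17 of 20 pericentral genes. Among wild-type vehicle livers 19 of 20 clock, 17 of 20 cholesterol and 18 of 21 replication genes also changed with time. For heat shock proteins this was 2 of 12 and for pericentral genes 2 of 20. For the former 3 lists the test does not separate a course of the CCl4 response from changes of the vehicle livers. Atf3 shows the course, with means of 14163.2, 18263.3 and 3339.9 counts in CCl4 livers at 4 h, 12 h and 24 h. Without the mice numbered below 7000 the count was 4656.

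**Figure D3:**
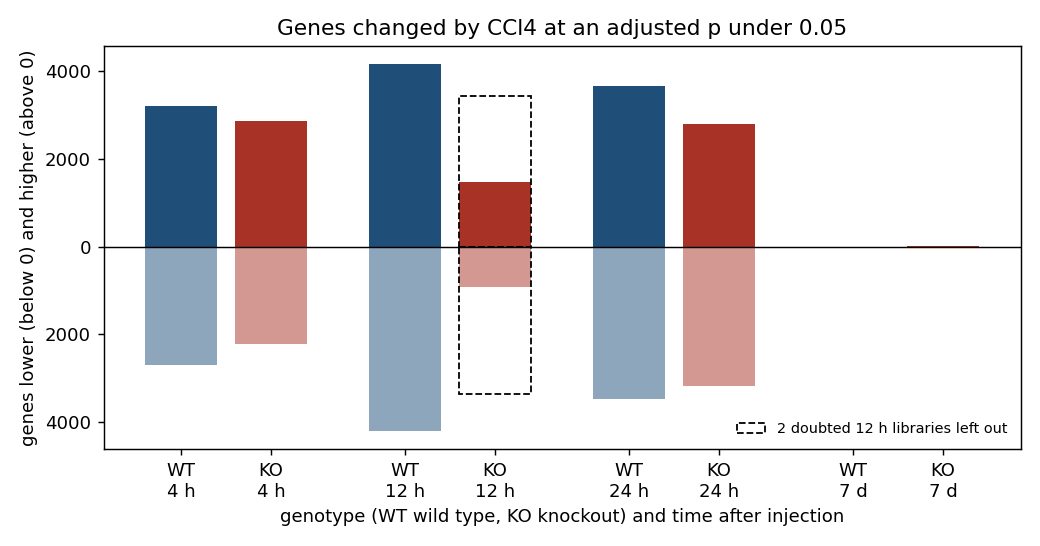
Number of genes changed by CCl4 at an adjusted p under 0.05 in each genotype and at each time, higher and lower. Wild type had 5896, 8365, 7163 and 7 changed genes, and the knockout 5097, 2397, 5978 and 55.

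In knockout livers the response to CCl4 was asked in the same way. At 4 h stress genes were again among the leading genes. Hspa1a rose by 7.48 ± 0.67, Fgf21 by 7.38 ± 0.73 and Cdkn1a by 5.97 ± 0.45, and Atf3 went from 213.4 ± 112.3 to 20505.3 ± 6418.7 counts (SD, n = 5; 6.70 ± 0.97). Dbp fell from 3994.2 ± 1809.1 to 566.2 ± 432.1 (-2.95 ± 0.71), and the thioesterase Acot3 fell by 3.56 on the log2 scale (SE 0.51). In total 5097 genes changed, 2872 higher and 2225 lower, or 44.5% higher in place of 56.3% with quantile normalization.

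Other large rises in the knockout at 4 h were those of Sprr1a (10.55 ± 1.78), Pwwp3b (6.48 ± 1.03), Slc7a11 (6.11 ± 1.07), Dusp5 (6.06 ± 0.80) and Psat1 (5.81 ± 0.82). Falls were seen for Unc79 (-3.52 ± 0.69), the neutrophil protease Prtn3 (-3.43 ± 0.75), Usp2 (-3.12 ± 0.31), Per3 (-3.07 ± 0.44), Tbx3 (-2.93 ± 0.32), the lipid receptor S1pr5 (-2.74 ± 0.42) and the signalling protein Wnt5b (-2.73 ± 0.37), with an adjusted p of at most 0.000706 (Dbp). All 12 heat shock proteins rose, with Hsph1 at 4.13 ± 0.37. In the unfolded protein list 18 of 20 genes rose and 1 fell, with Sesn2 at 3.99 ± 0.34, and 14 of 18 immediate early genes rose, with Ccn1 at 5.10 ± 0.53. Of 19 p53 targets 11 rose and 2 fell, with Gdf15 at 4.14 ± 0.51, and of 20 pericentral genes 7 fell. The camera adjusted p was 3.36e-16, 3.46e-08, 1.55e-08, 0.000387 and 0.000559, and with an estimated correlation the adjusted p was 0.0545, 0.199, 0.199, 0.0696 and 0.82. The counts were the same adjusted over the list alone. Of 23 interferon-stimulated genes 6 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.189), with Rsad2, an antiviral enzyme, at 3.05 ± 0.45 and Usp18, which removes ISG15, at 2.11 ± 0.31. In 1 vehicle library of this comparison, replicate 1, the X-inactivation RNA Xist, looked at after its values were seen, was 90.2 counts, against 3274 or more in each of the other 79 libraries.

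At 12 h the knockout groups as labelled gave 2397 changed genes, 1485 higher and 912 lower. Oat fell by 2.16 on the log2 scale (SE 0.41), Glul by 2.13 (SE 0.44) and Cyp2e1 by 1.51 (SE 0.31), and Atf3 rose by 4.87 ± 0.97. The library labelled CCl4 replicate 5 stood with the vehicle livers and the library labelled vehicle replicate 1 with the CCl4 livers. On a scale from 0 (wild-type vehicle) to 1 (wild-type CCl4), taken over 812 genes that changed in wild type, their positions were -0.02 and 1. The other CCl4 libraries of the knockout were at 0.69 to 1 and its other vehicle libraries at -0.05 to 0.04. With both libraries left out, an alternative chosen after their values were seen, 6805 genes changed, 3439 higher and 3366 lower, and 2396 of the 2397 were among them in the same direction. Atf3 then changed by 8.13, Oat by -3.53, Glul by -3.52, Cyp2e1 by -2.36 and Hspb1 by 6.41.

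**Figure D4:**
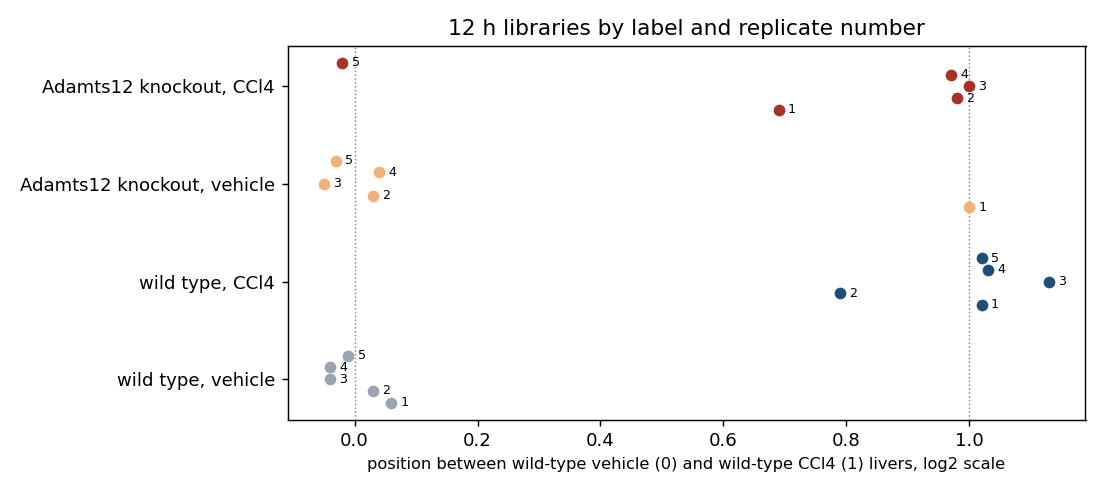
Position of each 12 h library between the wild-type vehicle mean (0) and the wild-type CCl4 mean (1), as the median over 812 genes. The library labelled knockout CCl4 replicate 5 lies at -0.02 and the library labelled knockout vehicle replicate 1 at 1.

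The rule for named genes asks for groups that do not overlap. At 12 h each knockout group as labelled holds a library that stood with the other treatment, so genes that follow CCl4 closely tend to overlap. The rule therefore passes over much of the response here, and the genes that met it as labelled were the following. Crym, a thyroid hormone binding protein, rose by 1.84 ± 0.38 and Sergef by 0.46 ± 0.16, while the interferon-induced GTPase Iigp1 fell by 0.83 on the log2 scale (SE 0.21) and Zfp292 by 0.59 (SE 0.18), with an adjusted p of at most 0.0446. Pericentral genes fell in 15 of 20 cases, heat shock proteins rose in 9 of 12, immediate early genes rose in 9 of 18, cytokines and chemokines rose in 9 of 21, and cholesterol genes fell in 7 of 20. By camera the adjusted p was 4.88e-10, 1.07e-06, 3.05e-06, 0.000241 and 4.98e-06, and with an estimated correlation the adjusted p was 0.392, 0.392, 0.392, 0.529 and 0.572. Adjusted over the list alone, 17 pericentral genes fell and 1 rose, 11 heat shock proteins, 9 immediate early genes and 11 cytokines rose, and 14 cholesterol genes fell. Without the 2 libraries 18 pericentral genes fell and 1 rose, 12 heat shock proteins and 13 immediate early genes rose, 14 cytokines rose and 1 fell, and 17 cholesterol genes fell. Sinusoidal markers fell in 0 of 18 cases as labelled by limma over all genes and in 8 without the 2 libraries. The count of 2397 was 299, 196, 579 and 5013 without CCl4 replicates 2, 3, 4 and 5, and 5443, 783, 939, 1185 and 563 without vehicle replicates 1 to 5.

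At 24 h knockout livers again showed low pericentral and high macrophage transcripts. Slc1a2 fell by 5.65 on the log2 scale (SE 0.40), Cyp2e1 by 3.63 (SE 0.31) and Glul fell by 4.05 (SE 0.44). Mmp12 went from 3.88 ± 3.63 to 699.5 ± 291.5 counts (SD, n = 5; 7.62 ± 0.91), and Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 6.27 ± 0.97. In total 5978 genes changed, 2811 higher and 3167 lower. Other large rises were those of Sprr1a (11.02 ± 1.78), Gsta1 (8.82 ± 1.09), Slc7a11 (7.71 ± 1.07), Bmp8b (7.00 ± 0.89), the growth factor Nrg1 (6.24 ± 0.75), Mmp13 (5.93 ± 0.75) and Foxred2 (5.80 ± 0.87). Large falls were those of Sult3a1 (-4.99 ± 1.18), Sult2a7 (-4.93 ± 0.76), the urinary protein gene Mup17 (-4.60 ± 1.42), Igdcc4 (-4.39 ± 0.92) and Cyp8b1 (-4.32 ± 0.66), with an adjusted p of at most 0.00715 (Mup17).

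Of 20 pericentral genes 17 fell and 1 rose in the knockout at 24 h. Monocyte and macrophage markers rose in 14 of 18 cases, with Cd68 at 2.84 ± 0.37. Cytokines and chemokines rose in 17 of 21 cases and fell in 1, with Ccl2, a chemokine for monocytes, at 3.78 ± 0.67 and Tnf at 3.25 ± 0.62. DNA replication genes rose in 16 of 21 cases and fell in 1, with the helicase subunit Mcm2 at 1.77 ± 0.25. The acute phase list fell in 18 of 23 genes and rose in 2, with Saa4 at -2.38 ± 0.41 and Cd14 at 4.80 ± 0.60. These falls are relative to oil-injected livers of 24 h, since acute phase genes of knockout vehicle livers changed with time in 21 of 23 cases. Bile acid genes fell in 13 of 18 cases and cholesterol genes in 15 of 20. The camera adjusted p of these 7 lists was 1.57e-10, 1.12e-08, 1.07e-06, 5.81e-07, 0.000145, 7.89e-07 and 2.87e-06. With an estimated correlation the adjusted p was 0.175, 0.175, 0.175, 0.175, 0.504, 0.175 and 0.462. Adjusted over the list alone, 15 macrophage markers, 18 cytokines and 17 replication genes rose, 20 acute phase and 16 cholesterol genes fell, and the other counts were the same. TGF-beta targets and ligands rose in 10 of 18 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00604, adjusted p = 0.175 with an estimated correlation).

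At 7 days the knockout had 55 changed genes, 25 higher and 30 lower, and 1581 genes had an unadjusted p under 0.05. Hspa5 stood at 14611.1 ± 3881.0 against 35299.3 ± 6185.0 counts (SD, n = 5; -1.29 ± 0.31), and Hyou1 (-1.42 ± 0.32), Manf (-1.28 ± 0.31), Hspa13 (-1.10 ± 0.23), the COPII coat subunits Sec23b (-1.23 ± 0.22) and Sec24d (-0.92 ± 0.22) and the oligosaccharyltransferase subunit Ostc (-0.82 ± 0.18) fell with it. Tfrc, the transferrin receptor, stood at 396.2 ± 135.1 against 1286.8 ± 224.2 (-1.73 ± 0.33), and the tRNA methyltransferase Mettl1 fell by 0.86 on the log2 scale (SE 0.22). Prob1 (0.97 ± 0.23), Zfp511 (0.84 ± 0.19), Mapk1ip1 (0.73 ± 0.18) and Zcchc8 (0.39 ± 0.09) rose. The adjusted p was 0.00207 to 0.046. Of 20 unfolded protein genes 3 fell, or 9 adjusted over the list alone (camera adjusted p = 1.36e-07, adjusted p = 0.34 with an estimated correlation). The count of 55 was 170, 6, 4 and 7 without CCl4 replicates 1, 2, 4 and 5, and 13, 14 and 117 without vehicle replicates 1, 2 and 3.

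Changed genes were shared between the genotypes at the 3 early times. At 4 h 2505 genes rose in both genotypes, where independent lists would share 631.7, 1662 fell in both (411.7), and 1 gene went in opposite directions. At 24 h 2320 rose (710.6) and 2626 fell (757.7) in both, with 0 opposite by limma in both. At 12 h, with the labels as given, 1458 rose (424.9) and 873 fell (263.1) in both. Across genes, which are not independent replicates, the log2 changes of the genotypes had a Pearson correlation of 0.86, 0.88, 0.91 and 0.24 at 4 h, 12 h, 24 h and 7 days.

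Whether loss of Adamts12 altered the CCl4 response was tested with the interaction of genotype and treatment, and limma called 1, 0, 0 and 1 genes at 4 h, 12 h, 24 h and 7 days. At an unadjusted p under 0.05 there were 553, 2643, 539 and 1398. The 12 h values include the knockout libraries that stood with the other treatment, so 0 and 2643 describe the groups as labelled. With both of these libraries left out, or with their labels exchanged, 0 genes were called at 12 h as well. Both settings were chosen after the values were seen. At 4 h the gene was Mcm6 (ENSMUSG00000026355, chromosome 1, 128331590 to 128359664), a subunit of the replicative helicase. CCl4 livers stood against vehicle livers at 555.1 ± 104.5 and 138.5 ± 25.9 counts in the knockout and at 43.7 ± 16.2 and 74.2 ± 45.7 in wild type (SD, n = 5), an interaction of 2.67 ± 0.49 (adjusted p = 0.0128). At 7 days it was Zfp429 (ENSMUSG00000078994, chromosome 13, 67387905 to 67399819), a zinc finger gene. It averaged 57.1 ± 10.6 after CCl4 and 12.2 ± 17 with vehicle in the knockout, and 51.4 ± 8.66 and 64.1 ± 13.7 in wild type, an interaction of 3.09 ± 0.51 (adjusted p = 0.00111). Mcm6 lay between 446 and 727 counts in the 5 knockout CCl4 livers and between 22 and 61 in those of wild type, and Zfp429 was at 3.7 to 5.8 in 4 of the 5 knockout vehicle livers and at 42.5 in the other. Both genes were also among the 67 that differed between the genotypes over all 8 conditions, described below. Mcm6 was higher in the knockout by 0.69 ± 0.12 (limma adjusted p = 0.000296). Zfp429 was lower, at -0.79 ± 0.13 (limma adjusted p = 4.77e-05). Whether their interactions come from loss of Adamts12 or from another difference of the knockout line was not tested.

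Among lists at 4 h, no member of the 23 interferon-stimulated genes passed for the interaction by limma over all genes, and 1 was higher adjusted over the list alone, while camera gave an adjusted p of 1.72e-06 toward a higher response in the knockout (median log2 0.69; adjusted p = 0.905 with an estimated correlation). At 24 h no sinusoidal marker passed over all genes or adjusted over the list alone, and camera gave 6.94e-10 (median 0.65; adjusted p = 0.756 with an estimated correlation). The F test over the 4 times called 1 gene, Zfp429 (adjusted p = 0.0407), or 0 without any 1 of 45 of the 80 libraries and 3 without wild-type CCl4 replicate 5 of 4 h. The 4 h count was 0 without CCl4 replicate 3 or vehicle replicate 5 of wild type or CCl4 replicate 2 or vehicle replicate 1 of the knockout, and 4 and 3 without CCl4 replicate 5 and vehicle replicate 1 of wild type. At 12 h the count of 0 became 188 and 20 without CCl4 replicate 2 and vehicle replicate 1 of wild type, and 148, 10 and 24 without CCl4 replicate 4 and vehicle replicates 4 and 5 of the knockout. Each of these 12 h fits still held both knockout libraries that stood with the other treatment. At 7 days the count was 2 and 3 without CCl4 replicate 4 and vehicle replicate 4 of wild type. Without the wild-type mice numbered below 7000 the interaction counts were 3, 57 and 0 at 12 h, 24 h and 7 days, the last 2 with a single wild-type vehicle liver at 24 h and a single wild-type CCl4 liver at 7 days, and array weights gave 11, 84 and 445 at 4 h, 12 h and 7 days. The 4 h gene was lost with quantile normalization. The 7-day gene was lost with a filter on a mean of 100 and with a fit of that time alone. At 12 h, 24 h and 7 days the wild-type CCl4 and vehicle groups differed in their share of mice numbered below 7000. The interactions at these times are therefore partly mixed with mouse number.

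The genotypes were then compared within CCl4 livers. At 4 h Mcm6 was higher in the knockout by 3.71 ± 0.35 (adjusted p = 5.56e-12), and Ctse, the protease cathepsin E, was 7.61 ± 3.37 counts in the knockout against 600.8 ± 219.7 in wild type (SD, n = 5; -6.13 ± 0.97). The clock activators were lower in the knockout, Arntl at 236.7 ± 149.6 against 790.8 ± 247.1 counts (-2.01 ± 0.33, adjusted p = 0.000125), Npas2 at -2.56 ± 0.52 and Clock at -0.70 ± 0.16. Usp18 was higher, at 1519.6 ± 398.9 against 609.8 ± 211.4 (1.36 ± 0.31, adjusted p = 0.0206). In total 57 genes differed, 22 higher and 35 lower in the knockout, and 1118 had an unadjusted p under 0.05. Of 20 clock genes 3 were lower, while adjusted over the list alone 5 were higher and 4 lower (camera adjusted p = 0.239). Of 23 interferon-stimulated genes 1 was higher, or 3 adjusted over the list alone (camera adjusted p = 3.36e-07, adjusted p = 0.846 with an estimated correlation).

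Other genes higher in the knockout CCl4 livers at 4 h were Susd4 (2.47 ± 0.54), the steroid hydroxylase Cyp2d9 (2.38 ± 0.54), the NADPH oxidase Nox4 (1.92 ± 0.48), Nbea (1.70 ± 0.35), the ribosomal protein gene Rpl26 (1.66 ± 0.28), the kinase Rps6ka1 (1.22 ± 0.30) and Slfn5 (0.98 ± 0.24). Lower genes were Prelid2 (-2.77 ± 0.46), Fam131c (-1.77 ± 0.40), the hyaluronidase Hyal1 (-1.26 ± 0.29), the Notch target Hes1 (-1.16 ± 0.27), Rnf144a (-1.14 ± 0.27), the WNT target Axin2 (-1.06 ± 0.24), the acetyltransferase Naa80 (-1.03 ± 0.24) and Zfc3h1 (-0.81 ± 0.20). The adjusted p was at most 0.0433 (Nox4). The count of 57 was 26 without wild-type replicate 1, and 34 and 26 without knockout replicates 3 and 4.

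At 12 h 64 genes differed between the genotypes in CCl4 livers as labelled, 13 higher and 51 lower in the knockout, and 2697 had an unadjusted p under 0.05. Wild-type replicates 1 and 2 were mice numbered below 7000 and no knockout mouse was, so genotype is partly mixed with mouse number here. Nbea, a membrane trafficking protein, was higher (1.72 ± 0.35), as were Zfp970 (1.24 ± 0.30) and Colgalt1, a collagen galactosyltransferase (0.45 ± 0.11). Blnk, a B cell adaptor, was lower (-2.41 ± 0.51), as were Serf1 (-1.17 ± 0.29), the exchange factor Dnmbp (-0.84 ± 0.16), Akt1s1, an inhibitor of mTORC1 (-0.79 ± 0.20), Vps72 (-0.68 ± 0.15), the clathrin light chain Cltb (-0.63 ± 0.16), the splicing factors Snrpd3 (-0.57 ± 0.14) and Sart1 (-0.55 ± 0.14), Hdgf (-0.55 ± 0.12) and Dus3l (-0.51 ± 0.12), with an adjusted p of 0.0148 to 0.0474. Without the 2 knockout libraries that stood with the other treatment 3 genes differed, Dnmbp (-0.88), Igf2bp3 (4.48) and Neurl3 (1.12), named after their values were seen. The count of 64 was 3, 945, 1, 7 and 3 without wild-type replicates 1 to 5, and 2, 293, 804 and 2 without knockout replicates 1, 3, 4 and 5.

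At 24 h the genotypes differed in CCl4 livers at Adamts12 itself (-2.21 ± 0.45, adjusted p = 0.0365) and at the predicted gene Gm28438 (4.36 ± 0.85, adjusted p = 0.0337), 2 genes in all, with 724 at an unadjusted p under 0.05. The count was 1, 0, 11 and 0 without wild-type replicates 1, 3, 4 and 5, 0 without knockout replicate 2, 3 or 4 and 73 without knockout replicate 5. At 7 days limma called 0 genes between the genotypes in CCl4 livers, with 861 at an unadjusted p under 0.05.

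Differences between the genotypes without injury were asked in vehicle livers. Over the mean of the 4 times 38 genes differed, 14 higher and 24 lower in the knockout, with 1244 at an unadjusted p under 0.05. Ide, the insulin-degrading enzyme, was higher by 0.90 ± 0.13 (adjusted p = 1.18e-05), at 2483.5 ± 273.8 against 1480.1 ± 407.7 counts at 4 h (SD, n = 5). The urinary protein gene Mup15 was lower (-3.82 ± 0.84), as were the acid phosphatase gene Acpp (-2.25 ± 0.54) and the transcriptional repressor Bcl6 (-1.22 ± 0.29). H2-Eb1, an MHC class II chain, was higher (0.81 ± 0.20). Tacc2 (-1.12 ± 0.23), the glycosyltransferase Ugt3a1 (-0.99 ± 0.24), the inflammasome gene Naip2 (-0.89 ± 0.21), Prob1 (-0.50 ± 0.11), the BMP inhibitor Smad6 (-0.44 ± 0.10), Zfp874a (-0.33 ± 0.07) and Rimoc1 (-0.31 ± 0.07) were lower. Ext1, which builds heparan sulfate (0.35 ± 0.08), Ppwd1 (0.33 ± 0.07), Clec16a (0.33 ± 0.08) and the peptidase Nln (0.22 ± 0.05) were higher. The unnamed transcripts A930036K24Rik (1.14 ± 0.24) and 4930556M19Rik (-0.83 ± 0.15) also differed, and the adjusted p was at most 0.0485 (H2-Eb1). No sinusoidal marker passed over all genes by limma and 3 of 18 were lower adjusted over the list alone (camera adjusted p = 1.25e-09, adjusted p = 0.871 with an estimated correlation). The share of called genes that were higher was 36.8%, or 51.4% with quantile normalization. Some wild-type mice of 24 h and 7 days were numbered below 7000 and no knockout mouse was, so genotype is partly mixed with mouse number here. This comparison also holds the library with low Xist and 1 of the 2 knockout libraries of 12 h that stood with the other treatment. Of the 38 genes 35 were still called without the 2 libraries of 12 h and 24 without these and the library with low Xist.

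**Figure D5:**
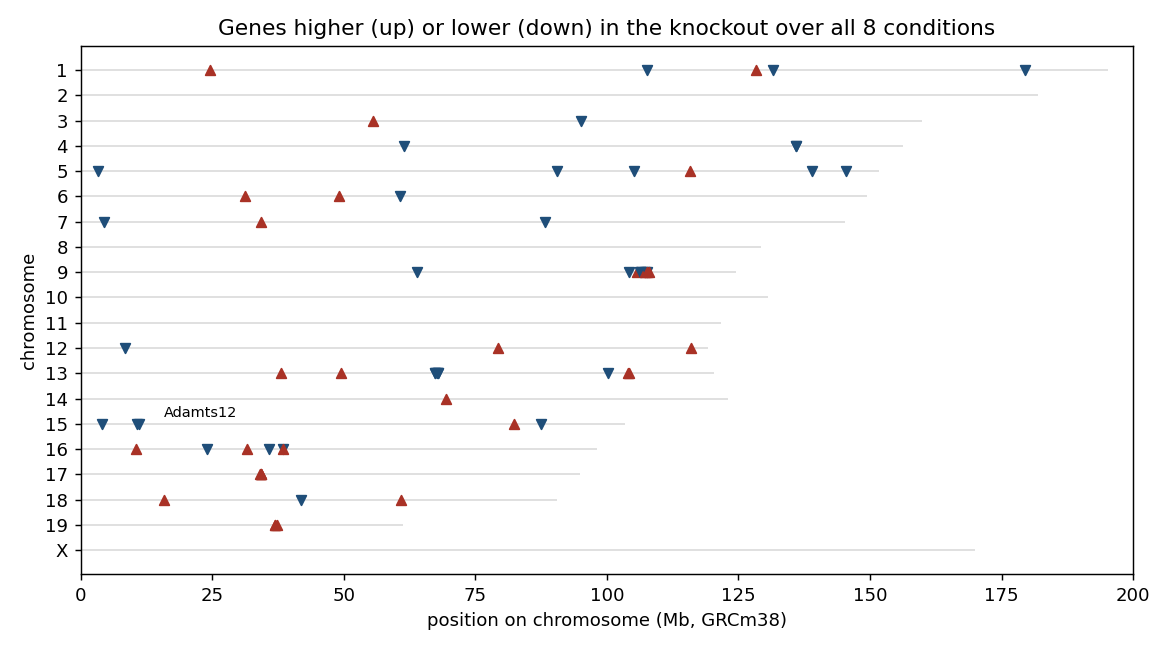
Positions of the 67 genes that differed between the genotypes over all 8 conditions, by chromosome in Mb of GRCm38, higher or lower in the knockout. Chromosomes 13 and 9 hold 10 of them each and chromosome 11 holds 0.

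At single times the vehicle livers of the genotypes differed at 24, 1, 0 and 8 genes at 4 h, 12 h, 24 h and 7 days by limma, with 1204, 1209, 1081 and 997 at an unadjusted p under 0.05. At 4 h 3 genes were higher and 21 lower, among them the phosphodiesterase Gdpd3 (-4.74 ± 0.93), AI480526 (-1.66 ± 0.39), Cdpf1 (-0.97 ± 0.19), Zmym6 (-0.85 ± 0.20) and Ttc14 (-0.69 ± 0.16), with an adjusted p of at most 0.0463. The predicted gene Gm28438 stood at 163.2 ± 49.6 counts in the knockout against 7.87 ± 4.73 (SD, n = 5; 4.41 ± 0.85). At 12 h Tafa5, a secreted chemokine-like protein, stood at 6.81 ± 1.59 in the knockout against 50.3 ± 12.1 (-2.70 ± 0.52, adjusted p = 0.0268). At 7 days Gm46620 (2.91 ± 0.46) and Ext1 (0.74 ± 0.16) were higher and Zfp874a was lower (-0.64 ± 0.14), with an adjusted p of at most 0.0474. Kupffer cell and monocyte markers were lower in the knockout at 24 h when adjusted over the list alone, in 8 of 13 cases with 1 higher and in 4 of 18, and in 0 over all genes. Of the 5 wild-type mice of this comparison 4 had numbers below 7000 and of the knockout mice 0, so genotype is mixed with mouse number here. Their camera adjusted p was 3.41e-06 and 3.53e-09, and the adjusted p was 0.309 for both with an estimated correlation.

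The counts in vehicle livers moved with single libraries. At 4 h the count of 24 was 14 without wild-type replicate 1 and 12 without knockout replicate 4. The count was 50 without the 2 knockout libraries of 12 h, which act on it only through the spread that all groups share. Without these and the knockout library with low Xist it was 45. At 12 h it was 13 without wild-type replicate 1, 0 without wild-type replicate 2, 3 or 4, 8 and 20 without knockout replicates 3 and 4, and 0 without knockout replicate 1, 2 or 5. At 7 days the count of 8 was 5, 2, 3 and 3 without wild-type replicates 1, 3, 4 and 5, and 3, 5 and 3 without knockout replicates 2, 4 and 5. At 24 h the count of 0 was 2 and 1 without wild-type replicates 2 and 4, 2 without knockout replicate 1, and 105 without the mice numbered below 7000, which leaves 1 wild-type liver.

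Vehicle livers themselves differed with time, at 4799 genes in wild type and 6785 in the knockout. The knockout vehicle livers include the 12 h library that stood with the CCl4 livers and the 4 h library with low Xist. Without the former the knockout count was 5655. Clock genes changed in 19 of 20 cases in wild type and 20 of 20 in the knockout, so time after injection is not separated from the state of the clock. Wild-type vehicle mice numbered below 7000 occurred at 24 h and 7 days and not at 4 h or 12 h. In wild type, time is therefore also partly mixed with mouse number. Dbp, taken up after its values were seen, was 4780.5 ± 1794.4 counts at 4 h and 38.5 ± 17 at 12 h in wild-type vehicle livers (SD, n = 5). Acute phase genes changed in 22 of 23 and 21 of 23 cases. Saa1, a serum amyloid, also chosen after its values were seen, was 76565.3 ± 48889.3 at 4 h, 419468.3 ± 244986.5 at 12 h, 495692.9 ± 50607.1 at 24 h and 2410.9 ± 1466.5 at 7 days in wild type (adjusted p = 2.02e-08), and 128844.5, 243911.6, 563329.3 and 5545.1 in the knockout (adjusted p = 3.23e-07). Lipogenesis genes changed with time in 11 of 13 cases in wild type and 13 of 13 in the knockout, and mitosis genes in 21 of 21 and 18 of 21. Without the mice numbered below 7000 the wild-type count was 2723.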

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

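The tests of explanations and the regroupings of libraries were chosen after the results were seen. Within groups of 5 livers, a library was called apart from its group at a gene when its gap to the nearest of the others, over the range of the group, passed Dixon's critical value of 0.71, which chance passes in about 1 in 20 groups. Over 144 named genes and 16 groups this happened in 195 of 2304 cases (8.5%). The library labelled knockout CCl4 12 h replicate 5 stood apart at 28 of the genes and the library labelled knockout vehicle 12 h replicate 1 at 23.

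These 2 libraries of the knockout at 12 h stood with the opposite treatment. On the scale from wild-type vehicle (0) to wild-type CCl4 (1) they were at -0.02 and 1, which points to a structure of the samples. The regrouping that exchanges them called 7861 genes for CCl4 in the knockout in place of 2397. A higher count follows from these positions, so it is not separate evidence for exchanged labels. A mixture of RNA from a treated and an untreated liver is argued against by genes that rose at least 16-fold in wild type, since the first library held -1.02% and the second 107.6% of the mean level above wild-type vehicle in the other knockout CCl4 libraries of 12 h, where an intermediate share is needed. An exchange of the labels of these 2 libraries is a candidate explanation, with both partners out of place in the other group. An injection that failed in one mouse together with a CCl4 injection given to a vehicle mouse stays open, as untested.

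The library labelled knockout vehicle 4 h replicate 1 had an Xist level of 0.65% of the median of the other 79 libraries. Of 11 measured genes with higher expression in male than in female liver, such as Cyp4a12a and Mup20, 10 were highest of all 80 libraries in this one, and 15 of 16 female-biased genes were lowest of the 10 vehicle libraries of 4 h. A male-like hormonal state in a female animal is argued against by Xist, whose lowest level in another library was 36.3 times as high. A male animal is a candidate explanation. Whether the mouse or the tube was in the wrong place was not tested.

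Genes that differed between the genotypes over all 8 conditions numbered 67, 31 higher and 36 lower in the knockout, and 28 of them had another within 1 Mb, where 10000 random sets had a median of 6 and at most 22 (permutation p = 1e-04, the smallest they can give). Examples are Zfp429 and Zfp874a on chromosome 13, Fgfbp3, Btaf1 and Ide on chromosome 19, H2-Ab1 and H2-Eb1 on chromosome 17, and 4930556M19Rik beside Adamts12 on chromosome 15. Copies of single gene families are argued against as the whole cause, since with 1 gene kept per family and no predicted genes 16 of 46 still had a neighbour (random median 2, highest 18, permutation p = 3e-04). Neighbours that vary together between livers are argued against too, since 1 of 100 labellings, the real one, had as many neighbours and the highest other had 17. Segments of another genetic background carried by the knockout line are a candidate explanation, and an effect of Adamts12 on genes near each other stays open.

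By the same rule for libraries apart from their group, wild-type CCl4 24 h replicate 3 had a normalized total of 22.5 M. Wild-type vehicle 4 h replicate 4 had 58 genes at 0. Knockout CCl4 24 h replicate 3 had 18.7% of its counts in its 10 most abundant genes. The rule was applied to 4 library measures in each of the 16 groups. At a rate of about 1 in 20, chance alone can give these few libraries. Of the differences between groups, the log2 CCl4 effect on Mcm6 was higher in the knockout than in wild type by 2.67 at 4 h, and that on Zfp429 by 3.09 at 7 days. Both genes are among the 67 that differed between the genotypes over all 8 conditions. The effect of CCl4 differed between times at 8802 genes in wild type. Gene lists whose response differed between the genotypes numbered 4, 14, 9 and 5 at 4 h, 12 h, 24 h and 7 days with camera's preset correlation and 0 with an estimated one. The 12 h number is for the groups as labelled, with the knockout libraries that stood with the other treatment.

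Each count of called genes was compared with those of 100 groupings of the same libraries, the real one included. The rule was that fewer than 5 groupings gave as many genes, which for a single count makes chance alone unlikely. No adjustment was made over the counts compared. Where the real count is 0, every grouping reaches it, so the comparison decides nothing there. The 7-day counts of wild type and of the interaction, 7 and 1 genes, were both 0 with a fit of that time alone. In wild type the rule held for CCl4 at 4 h (1 grouping, real count 5896, highest other 3177), 12 h (1, 8365 and 6121), 24 h (1, 7163 and 5984) and 7 days (2, 7 and 23). In the knockout it held at 4 h (1, 5097 and 2663) and 24 h (1, 5978 and 4001), and not at 12 h (19, 2397 and 7861) or 7 days (5, 55 and 297). For the interaction it held at 7 days (4, 1 and 2), and not at 4 h (5, 1 and 5), 12 h (100, 0 and 2754), 24 h (100, 0 and 1369) or over any time (17, 1 and 168). For the genotypes in CCl4 livers it held at 4 h (1, 57 and 11), and not at 12 h (12, 64 and 2740), 24 h (45, 2 and 2907) or 7 days (100, 0 and 2). In vehicle livers it held at 4 h (1, 24 and 11), 7 days (2, 8 and 30) and for the mean (1, 38 and 25), and not at 12 h (28, 1 and 266) or 24 h (100, 0 and 1). It held for the time dependence of the CCl4 effect (1, 8802 and 5056), for times among vehicle livers of wild type (1, 4799 and 229) and the knockout (1, 6785 and 2443), and for the genotypes over all 8 conditions (1, 67 and 4). The 194 list calls were reached by 60 groupings, with up to 242. For lists, genotype and treatment were redrawn together within each time, which mixes in the CCl4 effect, so this comparison cannot decide on chance. The groupings that called several times the real count at 12 h and 24 h point to a structure of the samples, which at 12 h includes the 2 libraries described.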

How the results depend on the processing

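Leaving out the libraries that stood apart was chosen after the results were seen, and the other alternatives were fixed beforehand. Of 963 alternative values of 26 counts and the Adamts12 level, 215 counts moved by over 1.5 times, and the other 748 were counts that did not or levels that kept their call and direction. Of 2701 list tests 2289 kept their call, 398 lost it and 14 turned direction, and of 16544 tests of named genes 15256 kept their call, 1287 lost it and 1 turned. TMM scaling and no filter moved no count. The tests on whole reads with edgeR and DESeq2 were not run. Where a cause is not given, the cause was not tested. The self-test recovered 20.9% of 1.5-fold and 95.5% of 4-fold differences for an interaction, so small interactions lie under the detection limit. Its changed genes had means of at least 100 counts and no library was out of place, so recovery in the real livers may be lower.

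An added threshold of 1 on the absolute log2 change, which can lower counts only, gave 2234, 4005 and 3206 genes for wild-type CCl4 at 4 h, 12 h and 24 h, 1756, 743, 2651 and 24 for the knockout at 4 h, 12 h, 24 h and 7 days, 18 for the genotypes in CCl4 livers at 12 h and 17 for the vehicle mean. A pseudocount of 8 gave an Adamts12 difference of -0.88 in place of -1.39, 11 for wild type at 7 days, 1 for the genotypes in CCl4 livers at 24 h, 5 in vehicle livers at 12 h and 0 for the interaction at any time.

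Without the wild-type mice numbered below 7000, which leaves fewer livers, with a lone vehicle liver at 24 h and a lone CCl4 liver at 7 days that are assumed to vary like the other groups, wild-type CCl4 gave 1302 at 24 h and 0 at 7 days. The interaction gave 3, 57 and 0 at 12 h, 24 h and 7 days and 31 over any time, the genotypes 252 and 1 in CCl4 livers at 12 h and 7 days and 4, 105 and 82 in vehicle livers at 12 h, 24 h and for the mean, the time dependence 4656 and the vehicle times of wild type 2723. Lists turned direction at an adjusted p of 0.809 for matrix genes in wild type at 24 h (range over its alternatives 0.0169 to 0.809), 0.129 for mitosis in wild type at 7 days (6.22e-14 to 0.538), 0.000461 for mitosis in the 7-day interaction (0.000461 to 0.96), 0.906 for interferon-stimulated genes between the genotypes in CCl4 livers at 7 days (0.00131 to 1) and 0.75 for cholesterol genes in vehicle livers at 24 h (2.02e-05 to 0.966). Retnlg, a neutrophil marker, turned from 1.43 to -0.59 in wild type at 24 h.

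A filter on a mean of 100, which tests fewer genes, gave 2 for wild type at 7 days, 0 for the interaction at 7 days and at any time, 31 and 0 for the genotypes in CCl4 livers at 4 h and 24 h, and 4, 0, 0 and 12 in vehicle livers at 4 h, 12 h, 7 days and for the mean. Quantile normalization gave 18 for wild type at 7 days, 0 for the interaction at 4 h and at any time, 37 and 0 for the genotypes in CCl4 livers at 4 h and 24 h, and 15, 5, 1 and 5 in vehicle livers at 4 h, 12 h, 24 h and 7 days. It moved the share of called genes that were higher from 56.3% to 44.5% for the knockout at 4 h, 54.3% to 45% for wild type at 4 h, 45.5% to 53.1% for the knockout at 7 days, 20.3% to 43.3% for the genotypes in CCl4 livers at 12 h, 12.5% to 26.7% and 0% to 40% in vehicle livers at 4 h and 12 h, 36.8% to 51.4% for the vehicle mean and 42.9% to 55.6% for wild type at 7 days. The median of all genes shifted by at most 0.06. A prior without trend gave 39 for the genotypes in CCl4 livers at 12 h. Replicate number as a block gave 0 for the interaction at any time, and an estimated correlation gave 0 list calls.

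Array weights gave 303 for wild type at 7 days, 8807 and 871 for the knockout at 12 h and 7 days, 11, 84 and 445 for the interaction at 4 h, 12 h and 7 days and 240 over any time, 366, 979 and 35 for the genotypes in CCl4 livers at 4 h, 12 h and 7 days, 235, 34, 342, 229 and 227 in vehicle livers at the 4 times and for the mean, and 9547 for the vehicle times of wild type. In the 12 h interaction pericentral genes turned at an adjusted p of 0.607 (range over its alternatives 0.0032 to 0.961) and heat shock proteins at 0.839 (0.000165 to 0.839), and bile acid genes turned in vehicle livers at 12 h at 0.856 (0.0128 to 0.856). A fit of each time alone, with fewer samples for the spread, gave 0 for wild type at 7 days, 0 and 15 for the knockout at 12 h and 7 days, 2 and 0 for the interaction at 4 h and 7 days, 86, 2, 0 and 1 for the genotypes in CCl4 livers at the 4 times, and 148 and 5 in vehicle livers at 4 h and 7 days.

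Without the 2 knockout libraries of 12 h that stood with the other treatment, counts were 6805 and 101 for the knockout at 12 h and 7 days, 3 for the genotypes in CCl4 livers at 12 h, 50 and 0 in vehicle livers at 4 h and 12 h and 2 for the interaction at any time. The counts of 101 and 50 moved only through the spread that all groups share. Pericentral genes in the 12 h interaction and bile acid genes in vehicle livers at 12 h turned, at 0.172 and 0.726. Without these and the library with low Xist the counts were 6814, 98, 2 for the interaction at 4 h, 2 for the genotypes in CCl4 livers at 12 h, and 45 and 4 in vehicle livers at 4 h and 12 h, and the lists turned at 0.174 and 0.744. Without the 2 and wild-type CCl4 12 h replicate 2 they were 12 for wild type at 7 days, 6850 and 106 for the knockout at 12 h and 7 days, 91 and 113 for the genotypes in CCl4 livers at 4 h and 12 h, 51 and 0 in vehicle livers at 4 h and 12 h and 2 for the interaction at any time, and the lists turned at 0.961 and 0.717.

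Leaving out a library at a time gave 5172 to 5799, 7624 to 8492, 6433 to 7674 and 1 to 550 genes for wild type at the 4 times, the last without CCl4 replicates 3 and 4. The knockout gave 4485 to 5065, 196 to 5443 (without CCl4 replicate 3 and vehicle replicate 1), 4728 to 6508 and 4 to 170 (without CCl4 replicates 4 and 1). The interaction gave 0 to 4, 0 to 188 (without wild-type CCl4 replicate 2), 0 to 0 and 1 to 3, and 0 to 3 over any time. The genotypes gave 26 to 67, 1 to 945 (without wild-type replicates 3 and 2), 0 to 73 (without knockout replicate 5) and 0 to 0 in CCl4 livers, and 12 to 33, 0 to 20, 0 to 2, 2 to 10 and 26 to 44 in vehicle livers at the 4 times and for the mean. Time dependence gave 8270 to 9127, vehicle times 4003 to 4946 and 5655 to 7313, list calls 187 to 208 and the Adamts12 difference -1.44 to -1.36. Libraries that moved a count by over 1.5 times are given with that count in the results, except for the interaction at any time, where 45 libraries that took the count to 0 are given as a number. Of 7570 such tests of named genes 880 lost their call.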

Other observations

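The counts of sex-biased genes, the Saa1 libraries and the tests of clock position were chosen after the results were seen, and the other lists were fixed beforehand. Genes with sex-biased expression in liver, 16 female-biased and 12 male-biased ones listed from general knowledge, were taken up for the library with low Xist. Of 16 measured female-biased genes 10 fell in wild-type livers at 12 h after CCl4, and 8 fell and 1 rose at 24 h in wild type and in the knockout. Of 11 measured male-biased genes 5 fell in wild type at 12 h, and 4 fell and 1 rose at 24 h. In the knockout at 12 h, where 2 libraries stood with the opposite treatment, 0 female-biased and 0 male-biased genes changed.

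Cholangiocyte markers moved in both directions in wild type after CCl4. Of 8 tested, 2 rose and 1 fell at 4 h, 3 rose and 1 fell at 12 h and 1 rose at 24 h, with camera adjusted p values of 0.753, 0.799 and 0.607. Sox9, a factor of biliary and progenitor cells, rose by 3.37, 2.37 and 2.26 on the log2 scale at these times (adjusted p = 5.14e-10, 2.18e-06 and 8.9e-06), Epcam rose by 2.27 at 4 h (adjusted p = 0.000117), and Krt23 changed by -3.13 at 4 h and 1.93 at 12 h (adjusted p = 0.00179 and 0.0427). Of 15 quiescent stellate cell markers 1, 7 and 5 fell at 4 h, 12 h and 24 h and 1 rose at 24 h (camera adjusted p = 0.708, 0.0194 and 0.171, and 0.517 at 12 h with an estimated correlation), with Cxcl12 lower at each time. At 24 h 5 of 17 T and NK cell markers and 4 of 10 neutrophil markers rose (camera adjusted p = 0.163 for each). Saa1 was low in single libraries of groups in which it was high, at 4458 counts in wild-type vehicle 12 h replicate 1, 1841 in knockout vehicle 12 h replicate 3, 2712 in wild-type CCl4 12 h replicate 2 and 4061 in knockout CCl4 24 h replicate 4.

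Because Arntl, Npas2 and Clock were lower in knockout than in wild-type CCl4 livers at 4 h, the position of each liver between wild-type vehicle livers of 4 h (0) and of 12 h (1) was taken over the 20 clock genes. After CCl4 the 4 h position was 0.4 ± 0.16 in the knockout and 0.69 ± 0.11 in wild type (SD, n = 5; exact permutation p = 0.0159, adjusted p = 0.0477 over 6 comparisons), with vehicle livers at 0.02 and 0 (exact permutation p = 0.73). The clock genes of the knockout may have moved less from the vehicle 4 h state, as a hypothesis found and tested on the same livers. Vehicle livers at 24 h also differed, at 0.83 ± 0.1 in the knockout and 0.61 ± 0.09 in wild type (exact permutation p = 0.0159, adjusted p = 0.0477), so a difference of the clock that does not need CCl4 stays open. At 24 h 4 of the 5 wild-type vehicle mice had numbers below 7000 and 0 of the 5 knockout ones, and a difference between these mice stays open too. At 7 days the exact permutation p was 0.286 after CCl4 and 0.111 with vehicle, and at 24 h after CCl4 it was 0.849.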
